A study of Mus musculus with 4 samples.

How the data were processed

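Epididymal adipose tissue of mice was profiled on 4 whole-transcript gene arrays, each hybridized with biotin-labelled cDNA made from 100 ng of total RNA. Per the labels' protocols, RNA of 4 to 6 mice per group was extracted with Trizol, purified on a column and pooled. The null allele of CD1d was on the C57BL/6J background after 10 to 12 generations of backcrossing. The diets, with 10 or 45 kcal% fat, ran for 18 to 19 weeks from an age of 10 to 11 weeks. Groups were taken from the sample titles: 1 wild type low-fat array, 1 wild type high-fat array and 2 KO low-fat arrays.

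The authors deposited 1 intensity per probe set and array on a linear scale. The arrays were summarized with the robust multi-array average (RMA) method in R 2.15.0, per the submitters' processing notes. The genome build and annotation release behind the probe sets are not given in the sources used here. The tests had been planned for deposited log2 values, and since the deposited intensities were linear, their log2 was taken first. No background correction, rescaling or new normalization was applied in the main analysis. The lowest intensity was 5.71 and the highest 20092, and the number of unmapped value columns was 0.

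Of 35556 probe sets, 21218 had 1 gene symbol in the platform annotation, 1881 had several and 12457 had none listed. The first kind was used, and no gene was named from a probe set with several symbols. Entrez IDs of 21185 probe sets matched the NCBI RefSeq gene table of assembly GRCm38.p6, which served for names and gene order and changed 0 symbols. For the 1386 genes with more than 1 probe set, the one with the highest mean over the 4 arrays was kept, giving 18820 genes. The 11292 genes with a mean log2 intensity of at least 5.45, the 40th percentile of those means, were tested.

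Comparisons between KO and wild type used limma 3.58.1 in R 4.3.3, with a mean for each of the 3 groups and eBayes without trend. The tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual degree of freedom, from the KO pair, beside 4.62 prior degrees of freedom and a prior SD of 0.28, so the lone wild type arrays were assumed to vary like the KO pair. Genes were also counted by size, at 1.5-fold or more, in the same direction on both KO arrays. The diet comparison has 1 array per group and was described by size only. Shared use of the wild type low-fat array was handled with 100 simulated sets of unchanged groups, whose noise came from the moderated spread of the KO pair and was drawn independently for each gene.

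Gene lists were 40 sets of markers, pathways and quality indicators with 584 genes, fixed before the data were examined. Of these genes, 515 had a probe set and 418 were tested. The 39 lists with at least 3 tested genes were analysed, and the list of mitochondrially encoded genes had 0 tested members. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The median of each list was also set among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. Neighbours of Cd1d1 were the 50 nearest tested genes on each side, and their median absolute change was ranked among windows of as many genes on other chromosomes.

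The named genes followed a rule fixed before the data were examined, leaving out predicted genes, small RNAs and olfactory or vomeronasal receptors. It took Cd1d1 and Cd1d2 always. For KO against wild type on the low-fat diet it took the 12 highest and 12 lowest among genes past the threshold, filled up where fewer passed by the largest change shared by both KO arrays. It took the 12 highest and 12 lowest in the diet comparison, 5 in each direction for KO against the high-fat array, and up to 4 members of each list. Genes named outside it are stated to have been chosen after their values were seen.

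Olfactory receptor genes and epididymal gene families were collected by symbol after the data were seen. The epididymal families also take in the seminal vesicle genes Svs2 and Svs5. The steps were tested on simulated data with 200 changed genes among 11292, for KO against wild type on the low-fat diet. The test recovered 0 of 50 genes changed 2-fold, 6 of 50 changed 4-fold, 39 of 50 changed 8-fold and 50 of 50 changed 64-fold, with 4 false calls. With 1 list shifted, camera called 1 list, while 8 lists lay outside the central 95% of random lists. Alternatives covered the low-signal filter, the probe set rule, centring or quantile normalization of the arrays, the variance model, the thresholds, the list test, the window size and each KO array left out, with several more added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.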

Results

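Gene expression was measured in epididymal adipose tissue, the visceral fat pad beside the epididymis, of wild type mice and of mice lacking CD1d. CD1d is an MHC class I-like molecule that presents lipid antigens to natural killer T (NKT) cells, and mice without it lack CD1d-restricted NKT cells. The series is about the part these cells play in adipose tissue and insulin resistance of lean mice. There were 4 arrays: 1 of wild type mice on a low-fat diet with 10 kcal% fat, 1 of wild type mice on a high-fat diet with 45 kcal% fat, and 2 of CD1d-null (KO) mice on the low-fat diet, called KO array 1 and KO array 2. KO mice on the high-fat diet were not analysed here, so the interaction of genotype and diet was not tested. The median intensity over 35556 probe sets was 51.9 on the wild type low-fat array, 51.1 on the wild type high-fat array, 52.2 on KO array 1 and 51.4 on KO array 2. Levels are log2 intensities, and differences are on the log2 scale unless given as a fold. Over the 11292 genes tested, the median difference from the wild type low-fat array was −0.17 on KO array 1, −0.02 on KO array 2 and 0.05 on the wild type high-fat array. The small number of arrays limits the precision, and wild type values have no replicate. The labels do not say whether the KO arrays held separate pools of mice, so p-values measure only the spread between these arrays. The source of that spread, technical or biological, is not known. It was large, with 2177 genes at least 1.5-fold apart between the KO arrays, against 1303 between the wild type arrays.

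Cd1d1, the gene disrupted in the KO mice, was high on both wild type arrays and near the bottom of the intensity range on both KO arrays. Its level was 11.80 on the wild type low-fat array and 11.80 on the wild type high-fat array, against 3.74 on KO array 1 and 3.98 on KO array 2 (KO mean 3.86 ± 0.17, SD, n = 2). The difference was −7.95, a 247-fold lower intensity, which is read as a lower bound because the KO mean lay at percentile 8.41 of gene levels. It was past the threshold in limma among the 11292 tested genes, with a standard error of 0.32 and an adjusted p = 0.00646, and not past it in the planned test over all 18820 genes, with a standard error of 0.24 and an adjusted p = 0.0932. Cd1d1 lies on chromosome 3 and was read by probe set 10499160 (Entrez gene 12479). The neighbouring copy Cd1d2 (probe set 10492957, Entrez gene 12480) was low on all 4 arrays, at 4.61 and 4.46 on the wild type low-fat and high-fat arrays and 4.50 and 4.18 on KO arrays 1 and 2, and was below the filter for testing.

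The KO arrays differed from each other in genes of macrophages, matrix and smooth muscle. On KO array 2, 18 of 22 macrophage markers, 9 of 14 genes of lipid-associated and CD11c-positive macrophages, 13 of 21 collagen and matrix genes and 7 of 11 cell cycle genes were at least 1.5-fold higher than on KO array 1. Itgax, the integrin CD11c of adipose macrophages and dendritic cells, was at 5.72 on KO array 1 and 8.72 on KO array 2, and the pan-macrophage marker Adgre1 (F4/80) at 8.23 and 9.95. In the opposite direction, 5 of 9 smooth muscle and pericyte markers were at least 1.5-fold lower on KO array 2, among them the contractile protein gene Cnn1, at 11.03 on KO array 1 and 5.12 on KO array 2. Relative to the median difference of all tested genes between these arrays, 0.14, the list medians lay at 0.84 for macrophage markers, 1.47 for lipid-associated macrophage genes, 0.66 for collagen and matrix genes, 0.68 for cell cycle genes and −0.94 for smooth muscle markers. In all, 2177 of 11292 genes were at least 1.5-fold apart, 1674 higher and 503 lower on KO array 2, and 1308 higher and 689 lower after quantile normalization. Pearson's r across genes, which are not independent replicates, was 0.943 for the KO pair and 0.949 between the wild type arrays. The wild type low-fat array gave 0.970 with KO array 1 and 0.962 with KO array 2. The wild type high-fat array gave 0.934 with KO array 1 and 0.981 with KO array 2. The spread in every test below comes from this pair.

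**Figure D1:**
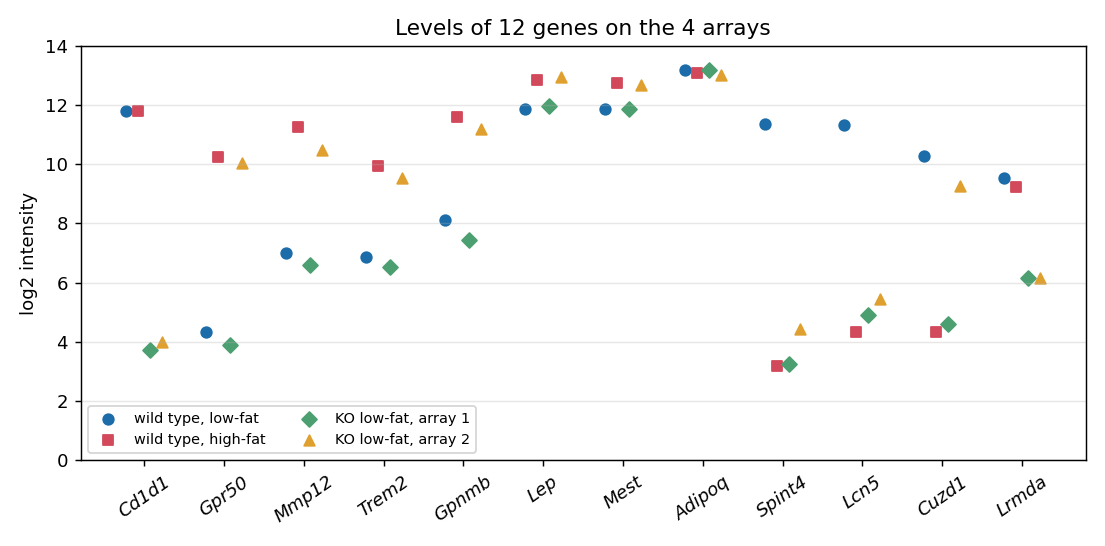
Log2 intensity (y axis) of 12 genes on the wild type low-fat array, the wild type high-fat array, KO array 1 and KO array 2, 1 point per array and no error bars. Cd1d1 was at 11.80 on both wild type arrays and at 3.74 and 3.98 on the KO arrays, while Mmp12 was at 7.01, 11.28, 6.59 and 10.49 in that order of arrays.

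The first comparison asks how wild type adipose tissue differed between the diets. Genes of lipid-laden macrophages were among the highest on the high-fat array against the low-fat array. Mmp12, a macrophage elastase, was at 7.01 on the low-fat and 11.28 on the high-fat array, 19.2-fold higher, and Atp6v0d2, a lysosomal proton pump subunit, was 20.6-fold higher. Gpnmb, a glycoprotein of lipid-loaded macrophages, was 11.1-fold higher and Trem2, a lipid-sensing receptor of macrophages, 8.43-fold higher. Gpr50, a melatonin receptor-related orphan receptor, was at 4.33 and 10.24, a 60.1-fold difference. Further genes among the 12 highest were Tm4sf19 (16.1-fold), Rgs1 (14.3-fold), a regulator of G protein signalling in immune cells, and the retinol dehydrogenase gene Dhrs9 (9.57-fold). The others were the interleukin-7 receptor gene Il7r (8.62-fold), the metalloprotease gene Adam8 (8.54-fold), Trdn (8.36-fold), which encodes triadin of the sarcoplasmic reticulum, and the kinase gene Cdkl4 (8.26-fold). The Trdn fold is from 1 of its 19 probe sets, the one with the highest mean. The low-fat levels of Gpr50, Tm4sf19 (5.51), Rgs1 (5.14), Dhrs9 (5.10) and Cdkl4 (4.60) lay under that array's median of 5.70, so their folds are read as lower bounds and their order is not established.

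Of the tested list members, 16 of 22 macrophage markers and 10 of 14 lipid-associated macrophage genes were at least 1.5-fold higher on the high-fat array, and 0 of either list were lower. Their medians, 0.90 and 1.70, lay above those of the central 95% of random lists, as did 8 other lists. These were cell cycle genes (1.02, 9 of 11 higher), pro-inflammatory cytokines and chemokines (0.64), adipose expansion genes (0.60), cholesterol synthesis genes (0.51), collagen and matrix genes (0.45), acute phase and secreted inflammatory proteins (0.39), dendritic cell and MHC class II genes (0.38) and interferon response genes (0.28). Lep, which encodes the satiety hormone leptin, was at 11.85 on the low-fat and 12.85 on the high-fat array, and Mest, a marker of fat cell enlargement, at 11.85 and 12.76. Ccl2, a monocyte-attracting chemokine, was at 7.79 and 8.82, and Ccl3 at 5.48 and 7.09, while Ptgs2, the inducible cyclooxygenase in the same list, was lower at 10.72 and 8.64. The proliferation marker Mki67 was at 5.88 and 7.17. In cholesterol synthesis, Hsd17b7 was at 7.06 and 8.34 and the sterol sensor Insig1 at 10.64 and 11.59. The acute phase gene Saa3 was at 6.83 and 9.22, Col6a1, a collagen VI chain abundant in adipose tissue, at 8.91 and 9.89, and Timp1, an inhibitor of matrix metalloproteases, at 5.85 and 7.31.

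On the lower side, 8 lists lay below the central 95% of random lists: epididymis and testis markers (−5.28), red blood cell genes (−0.59, 3 tested), thermogenic adipocyte genes (−0.38), mesothelial markers (−0.38), smooth muscle markers (−0.30), oxidative phosphorylation subunits (−0.29), ribosomal protein genes (−0.26) and NKT, T and NK cell markers (−0.22, with 0 of 12 at least 1.5-fold apart). Ndufa1, a subunit of respiratory complex I, was at 8.59 on the low-fat and 7.66 on the high-fat array, and Cidea, a lipid droplet protein of thermogenic fat, at 6.74 and 6.05. The 12 lowest genes all belonged to gene families of the epididymis, the sperm-storing duct to which this fat pad is attached. Ordered by measured difference they were Spint4 (287-fold lower), Lcn5 (130-fold), Epp13 (109-fold), Spint5 (92.5-fold), Spink11 (77.2-fold), Rnase12 (69.0-fold) and Defb23 (66.8-fold). The rest were Cuzd1 (61.9-fold), Adam7 (53.6-fold), Defb39 (46.3-fold), Wfdc10 (35.2-fold) and Defb30 (31.3-fold). Their levels on the high-fat array, from 3.19 to 5.37, lay under that array's median of 5.68, so these folds are read as lower bounds and their order is not established. They include protease inhibitors (Spint and Spink genes), beta-defensins (Defb genes) and a lipocalin (Lcn5). Epididymal markers thus differed beside every list named here, and 33 of the 55 genes at least 4-fold lower on the high-fat array were of epididymal families. The families were collected by symbol after the data were seen, so this count and the make-up of the 12 lowest genes in part restate that choice.

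The 21 other lists lay inside the central 95% of random lists. In simulated data for KO against wild type with 1 list shifted, 8 of the 39 lists lay outside, so a list outside is a description and not a test. The medians of the lists inside were 0.25 for CD1d and lipid antigen presentation, 0.23 for immediate-early genes, 0.20 for progenitor and fibroblast markers, 0.19 for sex-linked genes, 0.18 for hypoxia and 0.14 for fatty acid oxidation. They were 0.09 for fatty acid and triglyceride synthesis, 0.08 for insulin signalling, 0.07 for the unfolded protein response, 0.06 for lipolysis, 0.01 for neutrophil and eosinophil markers and 0.01 for mast cell markers. Negative medians were −0.05 for substrain-variable genes, −0.06 for B cells, −0.06 for circadian genes, −0.11 for alternatively activated macrophages, −0.24 for skeletal muscle, −0.27 for regulatory T cell and type 2 cytokine genes and −0.31 for pancreas markers. The medians of adipocyte identity genes, −0.01, and of endothelial markers, 0.03, changed sign with the scaling of the arrays, to 0.01 and −0.02 after quantile normalization. In all, 1303 genes were at least 1.5-fold apart, 872 higher and 431 lower on the high-fat array, which has no replicate check. The KO pair, of 1 genotype and 1 diet, gave 2177 such genes.

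**Figure D2:**
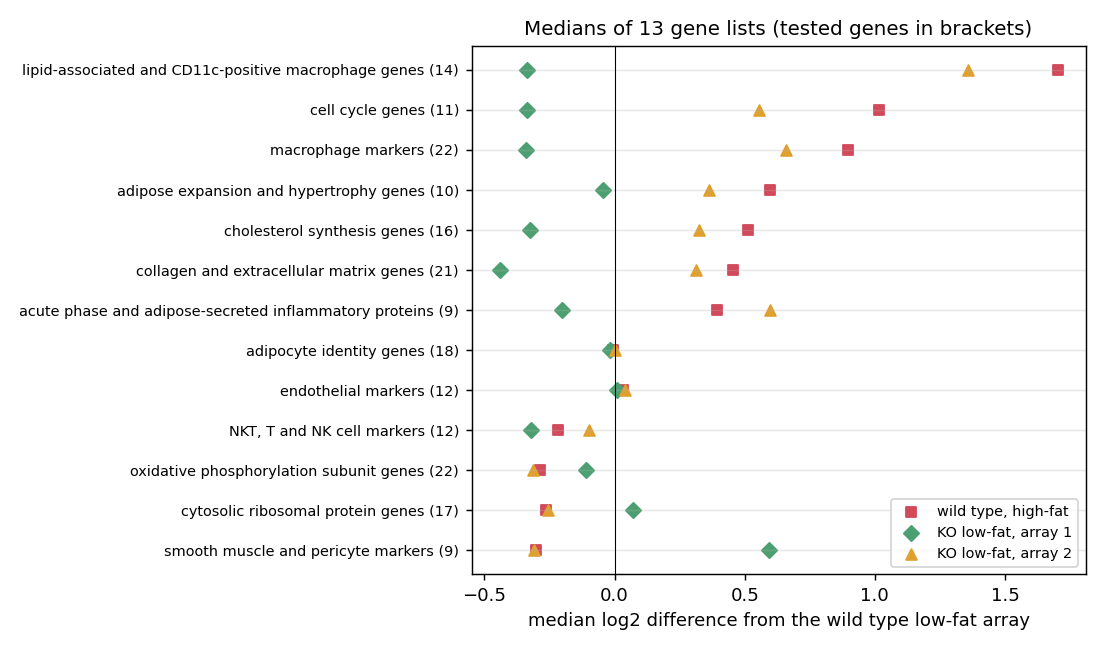
Median log2 difference from the wild type low-fat array (x axis) of 13 gene lists (y axis) on the wild type high-fat array, KO array 1 and KO array 2, 1 point per array. For lipid-associated macrophage genes the medians were 1.70, −0.34 and 1.36 in that order, and for smooth muscle markers −0.30, 0.59 and −0.31.

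The second comparison asks how adipose tissue without CD1d differed from wild type on the low-fat diet. Beside Cd1d1, 4 genes fell, all of epididymal families. They were the protease inhibitor genes Spint4 (from 11.35 to a KO mean of 3.84 ± 0.84, SD, n = 2) and Spint5 (10.75 to 4.57 ± 0.36). The others were the epididymal secretory protein gene Epp13 (11.80 to 5.47 ± 0.59) and the lipocalin gene Lcn5 (11.34 to 5.17 ± 0.39). In limma their adjusted p-values were 0.0292, 0.0193, 0.0292 and 0.0193. These genes were low on the wild type high-fat array as well, at 3.19, 4.22, 5.03 and 4.32 for Spint4, Spint5, Epp13 and Lcn5. The gene with the next largest shared change outside these families was Lrmda, a gene of melanocyte differentiation, at 9.54 on the wild type low-fat array and 9.25 on the wild type high-fat array against 6.17 and 6.14 on the KO arrays, with an adjusted p = 0.0962 in limma. The limma count was 0 higher and 5 lower, with 41 higher and 51 lower at an unadjusted p under 0.05. These 92 of 11292 genes are a smaller share than the 0.05 met among unchanged genes, so they are not read as further changes.

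Genes higher on both KO arrays did not pass the test, with an adjusted p = 1 in limma for each of the 12 named. They were the multi-copy Y-linked spermatid genes Srsy (1 of 13 probe sets, 6.68 on the wild type low-fat array, 8.85 and 8.21 on KO arrays 1 and 2) and Sly (1 of 8 probe sets, 7.32, 8.75 and 8.28), and the major urinary protein gene Mup6 (6.20, 7.68 and 7.61). The others were the alkaline phosphatase gene Akp3 (3.90-fold on KO array 1 and 2.29-fold on KO array 2), Itgad (1.75-fold and 4.80-fold), which encodes the integrin CD11d of macrophages, and Reg1 (3.81-fold and 2.02-fold). By the KO mean they also included the ceramidase gene Acer3 (2.34-fold), Krtap20-2 (2.23-fold), Igkv19-93 (2.20-fold), the glutamine transporter gene Slc38a3 (1.98-fold), Ada (1.77-fold), which encodes adenosine deaminase, and the fibrinogen gene Fgb (1.76-fold). The wild type low-fat levels of Akp3, Itgad, Reg1, Igkv19-93 and Slc38a3 lay under that array's median, so their folds are read as lower bounds. Of the 12 genes, Itgad, Slc38a3, Fgb and Acer3 were also higher on the wild type high-fat array than on the low-fat array, by 1.98, 1.49, 1.42 and 1.17. Further genes lower on both KO arrays were Defb23, Spink11, Rnase9, Rnase12 and Spink2 of epididymal families and the complement regulator gene C4bp, in that order. These genes were low on the wild type high-fat array as well, from 3.35 for Spink11 to 5.25 for Spink2, with C4bp at 5.01 there against 7.96 on the wild type low-fat array. Their differences from the wild type low-fat array on KO arrays 1 and 2 were −5.84 and −3.46, −3.38 and −5.74, −4.69 and −2.65, −4.78 and −2.26, −2.09 and −2.48, and −2.88 and −2.23. A size is read as a lower bound where its own KO level lay under that array's median. This holds for Defb23, Rnase9, Rnase12 and C4bp on KO array 1, for Spink11 on KO array 2 and for Spink2 on both. The 990 olfactory receptor genes, chosen after their values were seen, had a median of 0.35 on KO array 1 and 0.21 on KO array 2 relative to the wild type low-fat array. By size, 153 genes were at least 1.5-fold apart on both KO arrays, 66 higher, of which 25 had predicted or receptor symbols, and 87 lower, of which 21 were of epididymal families. Unchanged groups simulated with the spread of the KO pair gave a median of 854 genes apart on both KO arrays (803 to 914). KO array 1 alone gave 785 genes (218 higher, 567 lower) and KO array 2 alone 1145 (626 higher, 519 lower), both below the simulated median of 2255.5 (2077 to 2347) for 2 unchanged arrays. The simulated spread holds the difference between the KO arrays in macrophage, matrix and smooth muscle genes. Counts below it therefore do not show that KO and wild type differed less than replicates would.

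Of the 39 lists, camera placed 7 higher and 4 lower in KO at the preset correlation. With an estimated correlation, camera gave each of these lists an adjusted p = 0.979. That estimate rests on 1 residual degree of freedom and called 0 of the 39 lists, so it cannot decide for or against a call. The higher lists were lipid-associated macrophage genes (adjusted p = 0.000265), macrophage markers (0.00644), adipose expansion genes (0.00811), acute phase proteins (0.0250), neutrophil and eosinophil markers (0.0280, 3 tested genes), substrain-variable genes (0.0280, 4 tested genes) and cell cycle genes (0.0399). The first 4 of these lists and the cell cycle genes had medians of opposite sign on the KO arrays. Their medians were −0.34 on KO array 1 and 1.36 on KO array 2 for lipid-associated macrophage genes, −0.34 and 0.66 for macrophage markers, −0.04 and 0.36 for adipose expansion, −0.20 and 0.60 for acute phase proteins and −0.34 and 0.55 for cell cycle genes. Relative to all tested genes on each array, adipose expansion was at 0.13 and 0.39, of 1 sign, and the other 4 kept opposite signs. Cd68, a lysosomal macrophage protein, was at 10.09 on the wild type low-fat array, 9.53 on KO array 1 and 11.28 on KO array 2, and Lep at 11.85, 11.97 and 12.93. Lists with 1 sign on both KO arrays were neutrophil markers (0.79 and 0.06, with S100a8, a calcium-binding protein of neutrophils, at 5.88, 6.66 and 7.56) and substrain-variable genes (0.12 and 0.30, with Wdfy1 at 6.34, 6.99 and 7.31).

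The lower lists were epididymis and testis markers (adjusted p = 9.32e-12 in camera), red blood cell genes (0.0115, 3 tested genes), thermogenic adipocyte genes (0.0459) and oxidative phosphorylation subunits (0.0482). Each again had an adjusted p = 0.979 in camera with an estimated correlation, which cannot decide with 1 residual degree of freedom. Their medians on KO arrays 1 and 2 were −5.18 and −1.90, −0.40 and −0.81, −0.31 and −0.57, and −0.11 and −0.31. Relative to the median of all tested genes on KO array 1, oxidative phosphorylation subunits were at 0.06 there. Cidea was at 6.74 on the wild type low-fat array, 6.22 on KO array 1 and 5.45 on KO array 2, Ppargc1a, a coactivator of mitochondrial biogenesis, at 7.43, 6.88 and 6.87, and the heme synthesis gene Alas2 at 8.99, 8.29 and 7.76. In limma, list members past the threshold over all genes tested were 1 in the CD1d list, Cd1d1 itself, and 2 in the epididymis list, against 1 and 3 adjusted over the list alone, and 0 by both counts in the other lists. NKT, T and NK cell markers were not called, with medians of −0.32 on KO array 1 and −0.10 on KO array 2 (adjusted p = 0.440 in camera). On KO array 1, 3 of the 12 tested members were at least 1.5-fold lower and 1 was higher. Against the list medians, Zbtb16, the transcription factor PLZF of NKT cells, was at 10.29 and 10.23 on the wild type low-fat and high-fat arrays and 10.98 and 10.81 on the KO arrays. Its level was high in mice that lack CD1d-restricted NKT cells, so it is not read as a measure of those cells. The 5 genes called in limma became 1 without the epididymal families, 1 with each array centred on its median and 0 with no low-signal filter.

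The third comparison sets KO mice on the low-fat diet against wild type mice on the high-fat diet, which differ in genotype and diet together. Cd1d1 fell, with a difference of −7.95 and an adjusted p = 0.00646 in limma, and was the only gene past the threshold, with 0 higher and 1 lower (86 and 41 at an unadjusted p under 0.05). Those 127 of 11292 genes are again a smaller share than the 0.05 met among unchanged genes. With no low-signal filter 0 genes passed. The named genes in the higher direction were Wfdc10 (5.37 on the wild type high-fat array against 9.08 and 10.00 on KO arrays 1 and 2), Spink8 (6.52 against 11.68 and 9.63), the Ly6 family gene Ly6f (4.87 against 8.97 and 8.73), Wfdc15b (4.93 against 9.12 and 8.06) and the beta-defensin gene Defb11 (3.70 against 6.61 and 6.33). Of these 5 genes, 4 are of epididymal families. Lower on both KO arrays, beside Lrmda, were Svs2 and Svs5, which encode seminal vesicle secretory proteins (8.59 against 5.95 and 3.94, and 8.90 against 6.74 and 5.16), and the plasma protein gene Ambp (7.38 against 5.96 and 5.71). By size, 196 genes were at least 1.5-fold apart on both KO arrays, 107 higher and 89 lower. KO array 1 alone gave 2806 such genes, 515 higher and 2291 lower, and KO array 2 alone 325, 177 higher and 148 lower.

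Camera placed 6 lists higher and 5 lower in KO than on the high-fat array. The higher lists were ribosomal protein genes (adjusted p = 4.67e-05), epididymis markers (9.25e-05), oxidative phosphorylation subunits (0.000285), smooth muscle markers (0.000752), mesothelial markers (0.00147) and substrain-variable genes (0.0234). The lower lists were cell cycle genes (4.67e-05), macrophage markers (9.74e-05), collagen and matrix genes (0.000471), lipid-associated macrophage genes (0.000957) and cholesterol synthesis genes (0.00359). Each of the 11 had an adjusted p = 0.820 in camera with an estimated correlation. With 1 residual degree of freedom that setting called 0 of the 39 lists, so it cannot decide. Over all tested genes the KO mean lay at a median of −0.16 from the high-fat array. Relative to that shift the list medians were −0.60 for macrophage markers, −1.19 for lipid-associated macrophage genes, −0.35 for collagen genes, −0.62 for cell cycle genes and −0.31 for cholesterol synthesis. On the higher side they were 0.33 for ribosomal proteins, 0.30 for oxidative phosphorylation, 0.66 for smooth muscle, 0.91 for epididymis and 0.31 for substrain-variable genes. The mesothelial list had a median of −0.05, opposite in sign to its mean of 0.38 and its test, and of 0.11 relative to the shift. Most of these medians rest on KO array 1. Macrophage markers had a median of −1.23 from the high-fat array on KO array 1 and −0.20 on KO array 2. Relative to all tested genes on each array, lipid-associated macrophage genes were at −1.93 and −0.30 and collagen genes at −0.65 and 0.00. Cell cycle genes were at −0.88 and −0.17 and cholesterol synthesis genes at −0.52 and −0.09. Of the higher lists, ribosomal proteins were at 0.53 and 0.11, oxidative phosphorylation at 0.44 and 0.08, smooth muscle at 1.12 and 0.01 and mesothelial markers at −0.40 and 0.24. Epididymis markers, at 0.58 and 1.27, and substrain-variable genes, at 0.30 and 0.33, did not rest on KO array 1. At least 1.5-fold lower on both KO arrays were 0 of 22 macrophage, 0 of 21 collagen, 0 of 16 cholesterol synthesis, 3 of 14 lipid-associated macrophage and 2 of 11 cell cycle genes. Ctss, a macrophage protease, was at 10.31 on the high-fat array against 8.13 and 10.07 on KO arrays 1 and 2, and Tagln, a smooth muscle actin-binding protein, at 7.85 against 10.16 and 7.65. Limma members past the threshold were 1 over all genes tested and 1 adjusted over the list alone in the CD1d list, Cd1d1 itself, and 0 by both counts in the other lists.

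The fourth comparison asks whether genes that differed with the KO also differed with the diet. Across 11292 genes, which are not independent replicates, the mean KO difference and the diet difference, both taken against the wild type low-fat array, had a Pearson's r of 0.668 and a Spearman's rho of 0.585. Unchanged groups sharing that array gave a simulated median r of 0.578 (0.537 to 0.607), and the observed covariance, 0.108, was below the simulated median of 0.140, a difference of −0.03. The simulated spread came from the KO pair, whose arrays differed in whole groups of genes. A covariance below the simulated one therefore does not exclude a shared change. The KO arrays parted: r was 0.187 (rho −0.15) for KO array 1, the value without KO array 2, and 0.791 (rho 0.825) for KO array 2, the value without KO array 1. For 1 unchanged KO array the simulated r ran from 0.459 to 0.528, so KO array 1 lay below the simulated range and KO array 2 above it. Their covariances with the diet difference were 0.0370 and 0.180, against a simulated median of 0.140. Without the epididymal families r was 0.579 for the KO mean, −0.0858 for KO array 1 and 0.811 for KO array 2, and the covariance for KO array 1 was −0.0121, so its sign turned. Of the 872 genes at least 1.5-fold higher on the high-fat array, 43 were so on KO array 1 (16.8 for independent lists) and 490 on KO array 2 (48.3 for independent lists). For the 431 lower genes these numbers were 81 (21.6) and 277 (19.8). The shared low-fat array cannot be split, and part of each excess may come from it. The difference between the KO arrays shares no array with the diet difference, and its r with the diet difference was 0.517 (rho 0.703), against −0.06 to 0.09 in the simulations. Among the 872 genes higher with the diet, 680 (78.0%) were at least 1.5-fold higher on KO array 2 than on KO array 1, where 129 would be met in independent lists, and 218 of the 431 lower genes (50.6%) were lower, where 19.2 would be. The simulations and the independent-list numbers treat genes as unrelated, while genes can vary together. Neither is therefore a test of the correlations and overlaps given here.

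**Figure D3:**
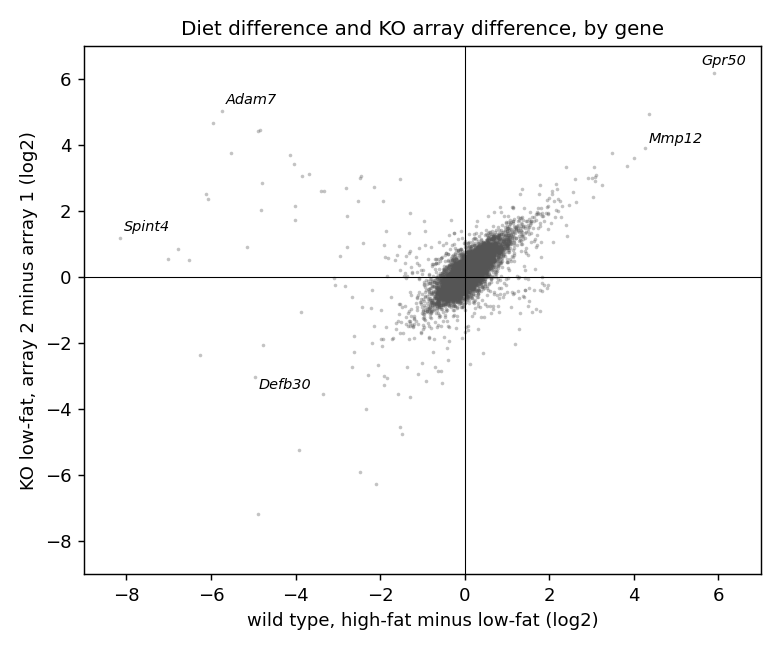
Log2 difference of the wild type high-fat from the wild type low-fat array (x axis) and of KO array 2 from KO array 1 (y axis), 1 point for each of 11292 genes. Macrophage genes such as Mmp12 lie high on both axes, and r across genes is 0.517.

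The last comparison looked for an effect on genes next to Cd1d1, since a backcrossed null allele carries flanking DNA of the strain it was made in. The 100 tested neighbours on chromosome 3 had a median absolute KO difference of 0.16, at percentile 71.0 of 8841 windows of as many genes on other chromosomes, and the diet difference of the same genes was at percentile 58.6. With 25 genes on each side the KO value was at percentile 97.6. Among the neighbours, Sfrp2, a secreted Wnt modulator, was at 8.96 and 8.89 on the wild type low-fat and high-fat arrays and 7.78 and 7.48 on KO arrays 1 and 2, and the thrombospondin gene Thbs3 at 7.26, 7.30, 6.08 and 6.26. Both genes were chosen after their values were seen, and neither passed limma's threshold (adjusted p = 1 for each).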

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

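The filter, scaling, probe set, variance, threshold, list test, window and left-out array alternatives were planned. Those without the epididymal gene families, with the wild type arrays as 1 group, for the correlation of the KO array difference, and with random-list percentiles for single KO arrays were added after the data were seen. In the planned tests 1 pair of arrays carries the spread, and 1 array stands for each wild type group. No paired analysis was possible because only the KO group has 2 replicate numbers and the wild type groups hold 1 array each. The list tests without a KO array could not be run, since 0 residual degrees of freedom remain, and the percentile among random lists took their place. Background signal was not analysed here, so low genes are limited by the filter alone.

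The 5 genes called in limma for KO against wild type on the low-fat diet became 0 with no filter, 2 with a filter at the 60th percentile and 3 with the mean of a gene's probe sets. They became 1 with each array centred on its median, 3 after quantile normalization, 1 with both wild type arrays as 1 group and 1 without the epididymal families. The 1 gene for KO against the high-fat array became 0 with no filter and 4 at the 60th percentile. Cd1d1 kept its difference, from −8.07 to −7.83 with a KO array left out, −7.94 with centring and −7.98 after quantile normalization. Of the 153 genes 1.5-fold apart on both KO arrays, the count was 287 with no filter, 50 at the 60th percentile, 43 at 2-fold and 785 to 1145 with 1 KO array (785 without KO array 2). Against the high-fat array 196 became 361, 61 and 71 under these settings in the same order and 325 to 2806 with 1 KO array (325 without KO array 1). The 1303 diet genes became 779 at the 60th percentile and 431 at 2-fold, and the 2177 genes between the KO arrays became 612 at 2-fold. The counts by size fall by construction with a stricter filter or a higher fold and grow with no filter, and for the other changes the cause was not tested.

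The correlation of KO and diet differences, 0.668, went from 0.187 without KO array 2 to 0.791 without KO array 1, and the correlation of the KO array difference with the diet difference, 0.517, stayed between 0.445 and 0.782. The 11 lists called for KO against wild type, 7 higher and 4 lower, became 3 with no filter, 0 higher and 3 lower. They became 7 at the 60th percentile, 7 after quantile normalization, 0 with an estimated correlation and 0 with fry, and 16 to 17 by random lists with 1 KO array (17 without KO array 2). The 11 lists against the high-fat array became 0 with an estimated correlation, 0 with fry, 18 by random lists and 15 to 17 by random lists with 1 KO array (17 without KO array 2). The estimated correlation and fry had 1 residual degree of freedom behind them, so their counts of 0 cannot decide. The 18 diet lists ranged from 12 to 19 over the alternatives. The Cd1d1 neighbours went from percentile 71.0 to 97.6 with 25 genes on each side, and lay between 17.5 and 93.1 under the other alternatives. Of 358 values of named genes under the alternatives, 358 had the sign of the main value. This largely follows from how the genes were chosen and is no check of them. The filter settings leave a gene's value as it is, and the named genes had large differences or changes shared by both KO arrays. Of the 148 that had a test, 130 kept their side of the threshold, 14 were no longer past it and 4 were newly past it.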

Other observations

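The gene lists were fixed before the data were examined, and all tests of explanations in this part were chosen after the results they concern had been seen. Beyond the comparisons made, KO array 1 stood apart in genes of contractile tissue. Smooth muscle markers had a median difference of 0.59 from the wild type low-fat array there, at percentile 100 of random lists, with Cnn1 at 8.05 on the wild type low-fat array and 11.03 on KO array 1 and Tagln at 8.25 and 10.16. Ptgs2 was at 10.72 on the wild type low-fat, 8.64 on the wild type high-fat, 12.41 on KO array 1 and 6.14 on KO array 2, and the transcription factor gene Gata3 at 7.22, 5.31, 8.46 and 5.20 in that order. The protamine gene Prm1, which packs DNA in sperm, was at 8.51, 8.63, 9.98 and 7.36. Endothelial markers had medians of 0.01 on KO array 1 and 0.04 on KO array 2, and 0 of 12 were 1.5-fold apart on either. On KO array 1, where all tested genes had a median of −0.17, their median was also above most random lists, at percentile 99.9.

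Some genes were lower on both KO arrays than on both wild type arrays in groups that did not pass as lists. Timd4, a receptor of resident macrophages, was at 6.89 and 6.50 on the wild type low-fat and high-fat arrays and 6.25 and 6.17 on KO arrays 1 and 2, and the eosinophil-attracting chemokine gene Ccl24 at 7.60, 7.31, 6.98 and 6.80. Neither gene was 1.5-fold apart with no overlap. Over all tested genes KO array 1 lay at a median of −0.23 from the wild type high-fat array, and the Timd4 difference there was of about that size. Both genes belong to the alternatively activated macrophage list, whose medians were −0.44 and 0.10 on the KO arrays. Counting genes at least 1.5-fold apart with no overlap for each way of splitting the 4 arrays into pairs gave 49 for wild type against KO, 606 for the wild type low-fat array and KO array 1 against the other pair, and 51 for the remaining split. The 3 splits are too few for a share under 0.05. The split with 606 genes points to a structure of the arrays that crosses the labelled groups.

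The second KO low-fat array lay close to the wild type high-fat array. If the knockout on low-fat diet shifted genes as the high-fat diet does, KO array 1 should show it, but over 395 genes at least 2-fold apart with the diet, epididymal families left out, its median ratio to the diet difference was −0.14. More macrophages alone would lower the lists of other cells alike, but between the KO arrays adipose expansion genes rose (median 0.59, quartiles 0.20 to 0.92) and smooth muscle markers fell (−0.79, −1.83 to 0.06), a gap of 0.14 between the nearer quartiles, the smallest over 3 scalings and against the wild type low-fat array. RNA of high-fat tissue on the array labelled KO low-fat 2 and fatter mice in that KO pool cannot be told apart: over the same 395 genes the median ratio of the KO array difference to the diet difference was 0.955 (quartiles 0.535 to 1.15), which restates the observation and goes with either. Cd1d1 was low on this array and present on the wild type high-fat array, which argues against a swap of those arrays.

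Epididymal transcripts were high on the wild type low-fat array. For the 6 tested list members, taken by their median, an effect of the diet alone is argued against by KO array 1, also on the low-fat diet. Their median there was −5.18 from the wild type low-fat array, and −1.90 on KO array 2. For the same members an effect of the knockout alone is argued against by the wild type high-fat array, at −5.28. A part of the epididymis in the wild type low-fat pool stays open: 4 of the 6 tested members were at least 4-fold higher there than on the wild type high-fat array and KO array 1, which restates the observation and does not test it. The list shares 0 genes with the other lists, and 2 of the 6, the testis genes Prm1 and Tnp1, were within 1.5-fold between the wild type arrays. List members under the filter for testing were low on the wild type low-fat array: Gpx5 (4.06), Lcn8 (4.04), Rnase10 (3.92), Lcn9 (4.13), Adam28 (4.22), Defb20 (5.08) and Cst11 (5.22). The filter favoured members with a high level on that array, so the 6 tested members and their medians do not stand for the whole list. Outside the list, 29 of 36 family genes on the wild type low-fat array, 9 on KO array 1 and 20 on KO array 2 were at least 4-fold above the wild type high-fat array. Some of these genes were low on the high-fat array only. Spink8 was at 6.52 there, against 11.30 on the wild type low-fat array and 11.68 and 9.63 on KO arrays 1 and 2. For such genes an effect of the diet stays open.

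Of the 39 genes at least 1.5-fold higher on both KO arrays than on both wild type arrays, 23 had predicted, small RNA or receptor symbols, and limma called 0 genes higher (41 at an unadjusted p under 0.05, a smaller share than among unchanged genes, KO against wild type on the low-fat diet). Some of the other genes also differed between the wild type low-fat and high-fat arrays, such as Ly6f (7.94 and 4.87) and Guca2b (7.45 and 6.03). Others, such as Akp3 (5.39 and 5.43), did not. The 39 genes may thus not share 1 source. More copies of Y chromosome families alone would not account for the 39 genes, since 15.4% of them lie on the Y chromosome. Wdfy1 of the substrain-variable list was among the 39, at 6.34 and 6.22 on the wild type low-fat and high-fat arrays and 6.99 and 7.31 on KO arrays 1 and 2. Strain background was not tested as a cause of the levels of these 39 genes. The camera call of the substrain-variable list for KO against wild type on the low-fat diet (adjusted p = 0.0280 at the preset correlation, 4 tested genes) and the Cd1d1 neighbours, both given above, do not settle it. Genomic DNA in the RNA of both KO arrays stays open: 990 olfactory receptor genes, a family mostly silent outside the nose, had medians of 0.35 and 0.21 above the wild type low-fat array on KO arrays 1 and 2, where 6559 other low-signal genes had 0.06 and −0.03, against −0.03 on the wild type high-fat array, which in part restates the observation and does not test it. The labels give 100 ng of RNA for each array. Differences between the KO and wild type arrays in hybridization, or in the RNA amount actually used, stay open and untested.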
